A study of Arabidopsis thaliana with 70 samples.

How the data were processed

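RNA was sequenced from Arabidopsis thaliana wild type (WT) and rdd, a ros1 dml2 dml3 triple mutant of DNA demethylase genes. The 38 RNA libraries fall into 14 groups. Seedlings, 10 days old, were sampled at 0, 1 and 3 h of 100 nM flg22, a peptide of bacterial flagellin, with 3 libraries per genotype and time. Leaves of 4-week-old plants were taken 24 h after hand inoculation with water or 100 nM flg22, with 3 libraries per group. In the priming set, leaves received water or flg22 and later the non-pathogenic Pseudomonas syringae strain DC3000 hrcC for 1 h, with 2 libraries per group. The remaining 32 of the 70 samples are whole-genome bisulfite libraries and were not used here.

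Per the submitters' processing notes, reads were processed with HISAT2, featureCounts and DESeq2 on the TAIR10 build; the notes give no versions. The deposited table names no unit. Its values have decimals, their totals lie between 904625 and 1231239 per library, and they behave as fragments scaled by gene length and by library total, so the deposited values were read as FPKM made by the authors. This reading is inferred from the values. The series table and the files of single libraries held the same values, with a largest difference of 0.0 FPKM. The table lists 33597 genes, of which 32830 (97.7%) were matched to a gene name, 279 are organelle genes and 8158 are at 0 in every library. All 715 genes shorter than 100 bp are at 0. In 56 genes with a median of at least 20 FPKM, 1 or more libraries are listed at 0. FPKM hold no read counts, so the sequencing depth of each library is unknown, no counting interval is given and no limit is set on values of 0.

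The tests planned for counts (edgeR) could not be used on FPKM, so the test laid down for scaled values was used. Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries (2 in the priming set) were kept. Each set of libraries was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend and robust variances), with 1 mean per group. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and a gene is called at an adjusted p under 0.05. The added 1 FPKM makes fold changes of weakly expressed genes smaller than the ratios of their means. Where nothing says that samples come from separate cultures or plants, the p-values measure only the spread between these samples.

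The comparisons were flg22 against no flg22 within each genotype, rdd against WT within each condition, and the genotype difference in the response, tested as an interaction. For seedlings no water-treated group at 1 h or 3 h is in the series, so time and the hour of sampling go with flg22. The series text states 3 repeats for RNA, while the priming set has 2 libraries per group.

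19 gene lists were fixed, holding 331 members. Before that 5 were left out because the annotation pairs their identifier with another symbol. They cover early MAMP-response markers (MAMPs are microbial molecules that plants sense), MAMP perception and signalling, salicylic acid and systemic resistance, jasmonate and ethylene, indole glucosinolate and camalexin, aliphatic glucosinolate, nuclear photosynthesis, auxin and expansion growth, the DNA methylation and demethylation machinery, loci with reported methylation-dependent expression, NLR immune receptors, apoplastic peroxidases and callose, abscisic acid and dehydration, the circadian clock, root markers, guard cell and stomatal lineage, phloem companion cell and epidermis, senescence, and cell division. Each was tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of 1 comparison, and again with the correlation estimated from the data. Counts of called members are given over all genes and adjusted over the list alone.

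The genes named in the text followed a rule. ROS1, DML2, DML3 and DME were named throughout. Per comparison, the rule took the 8 largest positive and 8 largest negative fold changes among called genes with at least 5 FPKM in the higher group, no overlap between libraries of both groups, and no organelle genes; interactions took the 8 smallest p in each direction. Per comparison and list it took up to 4 members with the smallest adjusted p. Among genes called in all 5 rdd against WT comparisons with 3 replicates it took up to 10 per direction. The lists, the rule, the comparisons, the tests and the first set of alternatives were chosen before the data were examined. The gene written NHL10 here carries the symbol YLS9 in the annotation.

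The size of the response was compared between genotypes over genes called and at least 2-fold changed in the average of both genotypes, with an exact permutation of the genotype labels within each condition. Overlaps between calls used Fisher's exact test, two-sided. Replicate numbers were checked for pairing across groups after group means were removed. In leaves, correlations between libraries with the same number ran from 0.313 to 0.904, all 18 above 0.1, so a fit with replicate number as a block is given beside the leaf results. In seedlings they ran from -0.272 to 0.33 with 10 of 45 above 0.1, and in the priming set from -0.104 to 0.111, so the numbers were not read as pairs there.

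Alternatives were median-ratio scaling of the libraries, no filter, organelle genes left out, replicate number as a block, only the compared groups in the fit, each library left out in turn, and, added after seeing the data, a pseudocount of 0.1 FPKM, leaf replicates 1 and 2 only, gene lists without doubted libraries and a permutation within replicate numbers. The procedure was tested on simulated data, with changes planted around the means and spreads of these genes. It recovered 72% of 2-fold and 98% of 4-fold changes in seedlings, 42% and 77% in leaves, and 90% and 99% in the priming set. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0 were also used.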

Results

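Messenger RNA was measured in Arabidopsis thaliana seedlings and leaves of wild type (WT) and of rdd, a triple mutant of the DNA demethylase genes ROS1, DML2 and DML3. The 18 seedling libraries came from 10-day-old plants at 0, 1 and 3 h of 100 nM flg22, a fragment of bacterial flagellin that plants sense through the receptor FLS2, with n = 3 per genotype and time. The 12 leaf libraries came from 4-week-old plants 24 h after water or 100 nM flg22, with n = 3 per group. In the 8 priming libraries, with n = 2 per group, leaves received water or flg22 and afterwards the bacterium DC3000 hrcC, which cannot inject effector proteins, for 1 h. Values were in FPKM. Gene levels are given as mean FPKM ± SD, and log2 fold changes of FPKM + 1 are followed by ± SE, with the n of the groups named above. The lists were tested with camera, and unless a p with an estimated correlation is given, a list that passed also passed with that. Where a single count of called members is given, the count adjusted over the list alone was the same. In the text of this section, genes measured at 0 in every library of a group are given as listed at 0, with no fold change.

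The genes mutated in rdd were measured first. ROS1 and DML2 were called lower in rdd in none of the 7 conditions, so their transcripts do not check the genotype labels. ROS1 (AT2G36490) transcripts stood at 7.22 ± 3.08 FPKM in rdd seedlings at 0 h and 6.8 ± 1.37 in WT. In water-treated leaves ROS1 stood at 27.7 ± 4.49 FPKM in rdd and 19.3 ± 1.4 in WT, a difference that did not pass the test (adjusted p = 1, limma). In the priming set ROS1 was higher in rdd both after water (log2 fold change 1.15 ± 0.14, adjusted p = 0.017, limma) and after flg22 (1.03 ± 0.14, adjusted p = 0.016). With 1 library left out the first call was lost in 4 of 4 fits and the second in 3 of 4. DML3 (AT4G34060) was at most 0.05 FPKM in seedlings, and in flg22-treated leaves it was lower in rdd, at 0.34 ± 0.08 against 2.83 ± 0.67 FPKM (log2 fold change -1.5 ± 0.19, adjusted p = 0.017; 0.26 with only the compared groups in the fit). DML2 (AT3G10010) and DME (AT5G04560), the demethylase that is intact in rdd, passed the test between genotypes in none of the 7 conditions.

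The first question was which genes respond to flg22 in WT seedlings within 1 h. Lists in which most genes rose included indole glucosinolate and camalexin (17 of 20), early MAMP-response markers (17 of 21) and MAMP perception and signalling (18 of 25). 1817 genes rose and 1443 fell at an adjusted p under 0.05 in limma, of 18886 tested, and 1128 rose and 313 fell by at least 2-fold. Without replicate 1 at 1 h 888 fell, and without replicate 3 at 0 h 935. The largest rises were in the oxidoreductase-like gene AT1G26380 (log2 fold change 7.33 ± 0.21), AT1G05675 (7.33 ± 0.22) and the transcription factor gene WRKY30 (AT5G24110, 7.01 ± 0.31, from 0.357 to 180 ± 58.1 FPKM). Close behind were the small heat shock protein gene HSP17.6A (AT5G12030, 6.76 ± 0.35), the glutamate decarboxylase gene GAD4 (AT2G02010, 6.70 ± 0.26) and the indole glucosinolate methyltransferase gene IGMT2 (AT1G21120, 6.68 ± 0.22, from 1.66 ± 0.18 to 275 ± 54.3 FPKM). Among the largest falls were GLYI7 (AT1G80160, -3.74 ± 0.34), EXO (AT4G08950, -3.09 ± 0.20) and the cell wall enzyme genes TCH4 (AT5G57560, -3.00 ± 0.21, from 74.5 ± 6.09 to 8.41 ± 0.694 FPKM) and XTH25 (AT5G57550, -2.73 ± 0.25).

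Among early MAMP-response markers 17 of 21 rose and 1 fell at 1 h in WT (median log2 fold change 1.87, camera adjusted p = 5.0e-17). They included CYP81F2 (AT5G57220, 5.58 ± 0.24), a cytochrome P450 that modifies indole glucosinolates, WRKY40 (AT1G80840, 4.49 ± 0.28), FRK1 (AT2G19190, 2.49 ± 0.47, 9.3 ± 7.82 against 0.573 ± 0.44 FPKM) and NHL10 (AT2G35980, 2.16 ± 0.18, 30.8 ± 8.68 against 5.93 ± 0.385 FPKM). MAMP perception and signalling had 18 of 25 higher and none lower, and 20 higher when adjusted over the list alone (median 1.93, camera adjusted p = 5.1e-24). Its members CPK28 (AT5G66210, 2.87 ± 0.11), BIR1 (AT5G48380, 2.72 ± 0.13), the ubiquitin ligase gene PUB22 (AT3G52450, 3.14 ± 0.17) and the kinase gene BIK1 (AT2G39660, 2.05 ± 0.10) all rose. Indole glucosinolate and camalexin genes had 17 of 20 higher (median 2.1, camera adjusted p = 1.0e-21). Among them were the sulfotransferase gene SOT16 (AT1G74100, 3.53 ± 0.16, from 87.8 ± 1.49 to 1038 ± 209 FPKM) and the transcription factor gene MYB51 (AT1G18570, 3.69 ± 0.18).

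In salicylic acid and systemic resistance 9 of 20 rose at 1 h, 10 adjusted over the list alone (median 0.77, camera adjusted p = 1.1e-05, adjusted p = 0.16 with an estimated correlation). They included the regulator genes CBP60G (AT5G26920, 2.04 ± 0.18), PAD4 (AT3G52430, 1.55 ± 0.15) and NPR1 (AT1G64280, 1.04 ± 0.16). In jasmonate and ethylene 10 of 25 rose, and 10 rose and 1 fell adjusted over the list alone (median 0.38, camera adjusted p = 0.00081, adjusted p = 0.45 with an estimated correlation). Members that rose were the lipoxygenase gene LOX4 (AT1G72520, 4.49 ± 0.24), the ethylene synthesis gene ACS7 (AT4G26200, 4.44 ± 0.35) and the repressor gene JAZ1 (AT1G19180, 2.73 ± 0.22). NLR immune receptors had 7 of 17 higher, 11 adjusted over the list alone (median 0.51, camera adjusted p = 8.9e-07, adjusted p = 0.18 with an estimated correlation), with ZAR1 (AT3G50950, 1.93 ± 0.17) and RPM1 (AT3G07040, 2.00 ± 0.21) among them. Apoplastic peroxidases and callose had 5 of 7 higher, 6 adjusted over the list alone (median 1.16, camera adjusted p = 1.7e-05, adjusted p = 0.078 with an estimated correlation), with PRX62 (AT5G39580) at 2.88 ± 0.26.

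Nuclear photosynthesis had 15 of 35 lower and none higher at 1 h in WT, 19 adjusted over the list alone (median -0.4, camera adjusted p = 8.9e-07, adjusted p = 0.16 with an estimated correlation). The antenna protein genes LHCB3 (AT5G54270, -1.58 ± 0.14, from 1023 ± 15.3 to 345.5 ± 54.6 FPKM) and LHCB4.2 (AT3G08940, -1.35 ± 0.13) were its leading members. Aliphatic glucosinolate genes had 6 of 11 lower and 1 higher (median -0.8, camera adjusted p = 0.010, adjusted p = 0.38 with an estimated correlation), with CYP83A1 (AT4G13770) at -1.46 ± 0.19. None of 33 genes of the DNA methylation and demethylation machinery changed (camera adjusted p = 0.88). Of 5 loci with reported methylation-dependent expression, 1 rose, RMG1 (AT4G11170, 0.96 ± 0.19), an NLR gene that reached 0.97 ± 0.267 FPKM (list camera adjusted p = 0.65). None of the remaining lists passed camera. With no water-treated seedlings at 1 or 3 h, flg22 and the hour of sampling cannot be told apart.

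By 3 h in WT seedlings 2279 genes rose and 1286 fell, 1106 and 253 of them by at least 2-fold (limma). Without replicate 1 at 0 h 828 fell, and without replicate 1 at 3 h 848. The higher share was 63.9%, 56.3% with median-ratio scaling and 74.1% with organelle genes left out. FRK1 (AT2G19190) rose by 6.15 ± 0.47 on the log2 scale, to 109 ± 20.2 from 0.573 ± 0.44 FPKM, and the chitinase family gene AT2G43620 rose by 6.30 ± 0.30, to 1750 ± 246 from 21.8 ± 7.22 FPKM. Heat shock genes AT1G53540 (7.15 ± 0.43) and HSP17.4 (AT3G46230, 6.45 ± 0.50) and the lipid transfer family gene AT4G22470 (6.05 ± 0.46) were among the largest rises. Among the largest falls were AT5G46900 (-3.18 ± 0.28), AT4G12520 (-2.63 ± 0.23), the arabinogalactan protein gene AGP22 (AT5G53250, -2.37 ± 0.38) and the root triterpene gene CYP705A5 (AT5G47990, -2.34 ± 0.34).

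At 3 h 17 of 21 early markers rose and 1 fell in WT (median 1.62, camera adjusted p = 2.0e-12, adjusted p = 0.05 with an estimated correlation), with CYP81F2 at 4.67 ± 0.24. Perception and signalling had 16 of 25 higher, 19 adjusted over the list alone (median 0.7, camera adjusted p = 1.3e-10, adjusted p = 0.05 with an estimated correlation), with PUB22 (3.10 ± 0.17) and LYK4 (AT2G23770, 1.75 ± 0.17), a chitin co-receptor gene. Indole glucosinolate and camalexin genes had 17 of 20 higher (median 2.47, camera adjusted p = 3.8e-22), with the tryptophan synthesis gene TSA1 (AT3G54640) at 406 ± 38.4 against 23.2 ± 1.89 FPKM (4.07 ± 0.22). Of peroxidases and callose 5 of 7 rose, 6 adjusted over the list alone (median 1.14, camera adjusted p = 3.6e-06, adjusted p = 0.05 with an estimated correlation). PRX71 (AT5G64120) reached 2675 ± 330 FPKM (4.07 ± 0.41) and PRX62 421 ± 9.8 FPKM (4.5 ± 0.26). In photosynthesis 25 of 35 fell, 30 adjusted over the list alone (median -0.61, camera adjusted p = 6.5e-17), with LHCB3 at -1.66 ± 0.14 and LHCB5 (AT4G10340) at -0.91 ± 0.14. Root markers had 5 of 16 lower, and 7 lower and 1 higher adjusted over the list alone (median -0.56, camera adjusted p = 2.7e-05, adjusted p = 0.06 with an estimated correlation), with PYK10 (AT3G09260) at 711 against 1311 FPKM (-0.88 ± 0.17). Auxin genes moved both ways, with 8 higher and 5 lower of 22, 8 and 6 adjusted over the list alone (camera adjusted p = 0.20). Salicylic acid genes had 11 of 20 higher, 12 adjusted over the list alone (camera adjusted p = 7.8e-06, adjusted p = 0.13 with an estimated correlation). Jasmonate and ethylene had 11 of 25 higher and 1 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 0.00030, adjusted p = 0.35 with an estimated correlation). NLR genes had 8 of 17 higher, 9 adjusted over the list alone (camera adjusted p = 0.00030, adjusted p = 0.35 with an estimated correlation).

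In rdd seedlings 1932 genes rose and 1243 fell at 1 h, 1171 and 247 by at least 2-fold, and 819 fell without replicate 2 at 1 h. The higher share was 60.9%, and 71.8% with organelle genes left out. The largest rises included WRKY30 (7.35 ± 0.31, 186 ± 18.6 against 0.14 FPKM), AT1G26380 (7.32 ± 0.21), HSP17.6A (6.97 ± 0.35) and IGMT2 (6.67 ± 0.22). TCH4 (-3.14 ± 0.21), XTH25 (-2.80 ± 0.25), the phosphate-induced gene PHI-1 (AT1G35140, -2.75 ± 0.19) and EXO (-2.47 ± 0.20) fell. Early markers had 17 of 21 higher and 1 lower, 17 and 2 adjusted over the list alone (median 1.83, camera adjusted p = 1.3e-14). Perception and signalling had 20 of 25 higher, 21 adjusted over the list alone (median 1.99, camera adjusted p = 8.1e-25). Indole glucosinolate and camalexin had 18 of 20 higher (median 2.66, camera adjusted p = 6.8e-25). CYP81F2 (5.54 ± 0.24), MYB51 (3.79 ± 0.18), CPK28 (2.98 ± 0.11) and SOT16 (4.06 ± 0.16) rose. Salicylic acid had 10 of 20 higher, 13 adjusted over the list alone (median 0.84, camera adjusted p = 9.3e-10), with PAD4 at 2.07 ± 0.15. Jasmonate and ethylene had 15 of 25 higher, 16 adjusted over the list alone (median 0.7, camera adjusted p = 9.3e-10, adjusted p = 0.10 with an estimated correlation). LOX4 (5.27 ± 0.24) rose, as did the jasmonate synthesis gene OPR3 (AT2G06050, 1.46 ± 0.15). All 7 peroxidase and callose genes rose (median 1.56, camera adjusted p = 4.0e-07). 10 of 17 NLR genes rose, 11 adjusted over the list alone (camera adjusted p = 3.2e-07, adjusted p = 0.15 with an estimated correlation). Photosynthesis had 14 of 35 lower, 25 adjusted over the list alone (median -0.47, camera adjusted p = 2.0e-09, adjusted p = 0.071 with an estimated correlation). Auxin genes had 2 of 22 higher and 5 lower, 2 and 9 adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.28 with an estimated correlation). That auxin call was lost with median-ratio scaling (adjusted p = 0.078) and without replicate 2 of rdd at 3 h (adjusted p = 0.071).

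At 3 h in rdd 1519 genes rose and 1517 fell, 749 and 343 by at least 2-fold. AT4G22470 (6.35 ± 0.46), AT2G43620 (6.18 ± 0.30), IGMT2 (5.78 ± 0.22) and FRK1 (5.30 ± 0.47, 66.6 ± 23.1 against 1.04 ± 1.67 FPKM) rose, and TCH4 (-2.60 ± 0.21) and the monoterpene synthase gene TPS-CIN (AT3G25820, -2.86 ± 0.78) fell. Early markers had 15 of 21 higher and 2 lower, 16 and 2 adjusted over the list alone (median 1.11, camera adjusted p = 5.5e-12, adjusted p = 0.07 with an estimated correlation), with CYP81F2 at 4.03 ± 0.24 and MYB51 at 3.40 ± 0.18. Perception and signalling had 16 of 25 higher, 18 adjusted over the list alone (median 0.67, camera adjusted p = 1.6e-15). Indole glucosinolate and camalexin had 17 of 20 higher, and 17 higher and 1 lower adjusted over the list alone (median 1.93, camera adjusted p = 1.9e-27), with CYP83B1 (AT4G31500, 3.26 ± 0.17). Photosynthesis had 18 of 35 lower, 23 adjusted over the list alone (median -0.46, camera adjusted p = 3.7e-07, adjusted p = 0.15 with an estimated correlation). Abscisic acid and dehydration had 4 of 10 lower, 5 adjusted over the list alone (median -0.88, camera adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation). These included the phosphatase genes HAI1 (AT5G59220, -1.27 ± 0.26) and ABI2 (AT5G57050, -1.06 ± 0.22). The share of called genes that were higher was 50% here, 62.5% with median-ratio scaling and 61.4% with organelle genes left out. Without replicate 1 at 0 h 1395 rose and 2744 fell (33.7% higher), and without replicate 3 at 3 h 37.3% were higher. Without replicate 2 at 0 h, replicate 3 at 0 h or replicate 2 at 3 h 790, 802 and 782 genes fell. The median log2 fold change of all genes was -0.142. Replicate 2 of rdd at 3 h stood apart, with 2.855% of FPKM in organelle genes against 0.223% to 0.809% in the other seedling libraries and with the fewest genes above 0, at 18555. Without replicate 3 of rdd at 0 h, 1971 genes were called, and with only the compared groups in the fit 894, when TPS-CIN and ABI2 did not pass (adjusted p = 0.088 and 0.051).

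**Figure D1:**
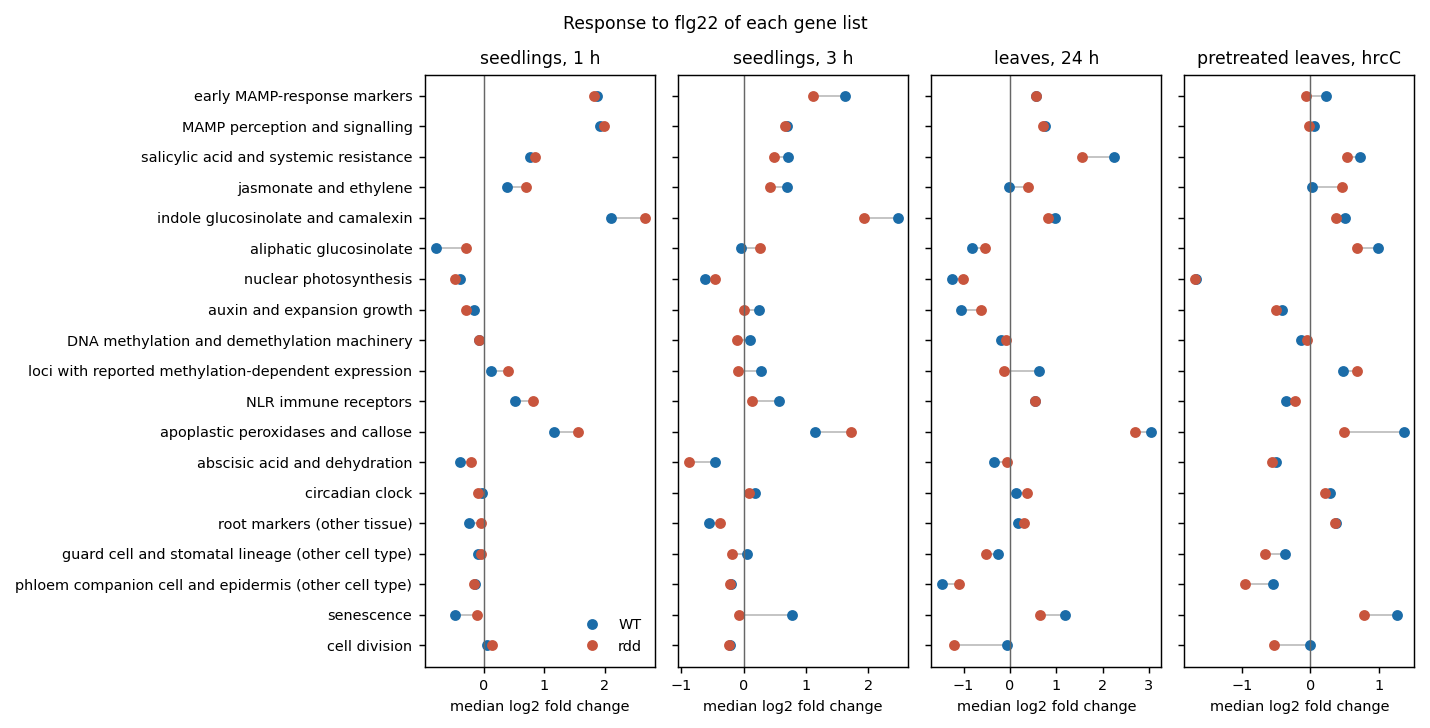
Median log2 fold change after flg22 of the measured genes of the 19 gene lists (horizontal axis, log2 of FPKM + 1), with WT in blue and rdd in red, in 4 panels by sampling. Points are list medians; indole glucosinolate and camalexin reached 2.1 in WT at 1 h and nuclear photosynthesis was below 0 in every panel.

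What rdd changes without a stimulus was asked in seedlings at 0 h. A small set of genes differed, mostly lower in rdd: 44 genes were lower and 17 higher, 31 and 12 of them by at least 2-fold (limma). AT3G01345 was the most reduced, at 0.047 against 111 ± 15.1 FPKM (log2 fold change -6.74 ± 0.14, adjusted p = 5.8e-15). MRD1 (AT1G53480, -5.84 ± 0.17, 65.7 ± 4.4 FPKM in WT) and the cysteine-rich receptor-like kinase gene CRK40 (AT4G04570, -3.92 ± 0.20) were lower. So were the methionine sulfoxide reductase gene MSRB5 (AT4G04830, -3.70 ± 0.26), AT4G07820 (-3.64 ± 0.44), AT1G67105 (-3.19 ± 0.33) and AT2G33830 (-3.15 ± 0.15, 603 ± 68.3 against 5389 ± 932 FPKM). AT4G04223 was listed at 0 in rdd and at 8.76 FPKM in WT. Higher in rdd were the potassium transporter gene HAK5 (AT4G13420, 2.54 ± 0.16, 18.7 ± 2.17 against 2.38 ± 0.136 FPKM), CYP97B3 (AT4G15110, 1.96 ± 0.35) and the zinc transporter gene HMA2 (AT4G30110, 1.79 ± 0.28). TMM (AT1G80080), a receptor-like gene of stomatal patterning, was higher too (1.41 ± 0.14, 43.3 ± 3.08 against 15.7 ± 1.81 FPKM).

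By list, jasmonate and ethylene had 2 of 25 lower at 0 h, 7 adjusted over the list alone (median -0.34, camera adjusted p = 2.6e-09, adjusted p = 0.24 with an estimated correlation). They were the synthesis genes OPR3 (-0.87 ± 0.15, 21.0 ± 0.375 against 39.8 ± 6.6 FPKM) and AOC1 (AT3G25760, -1.37 ± 0.27). Loci with reported methylation-dependent expression had a median of -0.63 (camera adjusted p = 0.00019), with 0 of 5 called over all genes and 3 lower adjusted over the list alone. Among them EPF2 (AT1G34245), a peptide gene that limits stomatal number, stood at 0.813 against 3.56 FPKM (-1.31 ± 0.34, adjusted p = 0.18) and QQS (AT3G30720) at 0.07 against 1.02 FPKM (-0.92 ± 0.31, adjusted p = 0.46). Aliphatic glucosinolate (median -0.34, camera adjusted p = 2.6e-09, adjusted p = 0.054 with an estimated correlation) and photosynthesis (median -0.14, camera adjusted p = 7.6e-06, adjusted p = 0.26 with an estimated correlation) shifted without any called member. Root markers shifted too (median 0.26, camera adjusted p = 0.033, adjusted p = 0.45 with an estimated correlation). The expansin gene EXPA8 (AT2G40610) was lower (-1.32 ± 0.16, 18.7 ± 0.49 against 48.4 ± 6.38 FPKM). Of 10 guard cell and stomatal lineage genes TMM was higher, or 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.058). With 1 library left out 9 to 15 genes were higher and 25 to 41 lower. The count of 61 genes fell to 34 without replicate 3 of WT and to 40 without replicate 3 of rdd at 0 h, and with only the compared groups in the fit it was 26, when OPR3, AOC1 and CYP97B3 did not pass (adjusted p = 0.12, 0.4 and 0.23).

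At 1 h of flg22, 31 genes were lower and 23 higher in rdd, 31 and 14 by at least 2-fold. NHL10 (AT2G35980), a flg22-induced marker, was among the lower ones at 5.87 ± 0.679 against 30.8 ± 8.68 FPKM (-2.18 ± 0.18, adjusted p = 2.3e-06, limma). CRK39 (AT4G04540) was at 1.73 ± 0.416 against 24.9 ± 3.92 FPKM (-3.25 ± 0.18, adjusted p = 6.6e-09). MRD1 (-6.01 ± 0.17), CRK40 (-4.14 ± 0.20), MSRB5 (-3.96 ± 0.26) and AT2G33830 (-3.08 ± 0.15) were again lower, and AT3G01345 was listed at 0 in rdd. HAK5 (2.32 ± 0.16), HMA2 (2.05 ± 0.28), GLYI7 (1.7 ± 0.34), the cell wall-associated kinase gene WAK1 (AT1G21250, 1.49 ± 0.26, 21.2 ± 7.04 against 6.92 ± 2.31 FPKM) and TMM (1.27 ± 0.14) were higher. Photosynthesis passed camera with no called member, or 7 lower adjusted over the list alone (median -0.15, camera adjusted p = 2.3e-08, adjusted p = 0.21 with an estimated correlation). So did root markers with none called, or 2 higher adjusted over the list alone (median 0.43, camera adjusted p = 0.00069, adjusted p = 0.21 with an estimated correlation). Salicylic acid genes (median 0.4, camera adjusted p = 0.012, adjusted p = 0.55 with an estimated correlation) and methylation-dependent loci (median -0.31, camera adjusted p = 0.047, adjusted p = 0.21 with an estimated correlation) passed too, the loci not with median-ratio scaling (adjusted p = 0.41). With 1 library left out 7 to 22 genes were higher and 20 to 25 lower. The count of 54 was 29 without replicate 3 of WT and 27 without replicate 1 of rdd at 1 h, and the median log2 fold change of all genes was 0.111. GLYI7 did not pass with median-ratio scaling (adjusted p = 0.12) nor WAK1 with a pseudocount of 0.1 FPKM (adjusted p = 0.068).

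At 3 h of flg22, 104 genes were lower and 76 higher in rdd, 83 and 28 by at least 2-fold. NHL10 stood at 3.47 ± 0.557 against 27.8 ± 2.27 FPKM (-2.69 ± 0.18, adjusted p = 1.3e-07), MRD1 at -5.81 ± 0.17, CRK40 at -4.05 ± 0.20 and AT2G33830 at -3.29 ± 0.15. The peroxidase gene PRX5 (AT1G14550) was lower (-1.97 ± 0.34), and AT3G01345 and AT4G04223 were listed at 0 in rdd. Of 5 methylation-dependent loci 2 were lower (median -0.61, camera adjusted p = 0.012, adjusted p = 0.13 with an estimated correlation). They were EPF2 (-1.73 ± 0.34, 0.733 ± 0.666 against 4.60 ± 1.6 FPKM) and RMG1 (-0.91 ± 0.19, 0.367 ± 0.318 against 1.53 ± 0.223 FPKM). HAK5 (2.60 ± 0.16), AT5G46900 (2.28 ± 0.28), CYP705A5 (1.7 ± 0.34), AT4G12520 (1.57 ± 0.23) and TMM (1.51 ± 0.14) were higher. Root markers of the fixed list had none of 16 called over all genes and 5 higher adjusted over the list alone (median 0.41, camera adjusted p = 1.3e-05, adjusted p = 0.13 with an estimated correlation). Senescence genes had none of 5 called and all 5 lower adjusted over the list alone (median -1.02, camera adjusted p = 0.0021, adjusted p = 0.27 with an estimated correlation). The count of 180 was 124 without replicate 2 of rdd, the library with the high organelle share, where the balance turned to 69 higher and 55 lower, 1709 without replicate 3 of rdd and 65 without replicate 2 of WT, and with only the compared groups in the fit it was 30 (45 at 1 h), when EPF2, RMG1, CYP705A5, PRX5 and AT4G12520 did not pass. It was 81 without replicate 1 of WT, 77 without replicate 3 of WT and 83 without replicate 1 of rdd, and 283 with median-ratio scaling, where the median log2 fold change of all genes was -0.137 before scaling.

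Whether flg22 acted differently in rdd was tested as an interaction. At 1 h 2 genes passed in limma: CRK39, listed at 0 in rdd before flg22, responded less in rdd (adjusted p = 7.8e-06), and so did NHL10 (difference of log2 fold changes -2.58 ± 0.25, adjusted p = 0.00015). NHL10 rose in WT but stood at 8.23 ± 1.13 FPKM before flg22 and 5.87 ± 0.679 FPKM at 1 h in rdd. At 3 h NHL10 alone passed (-3.10 ± 0.25, adjusted p = 2.1e-05). NHL10 lies 60 genes from ROS1 on chromosome 2. FRK1, CYP81F2 and MYB51 did not pass at either time, and CRK39 did not with a pseudocount of 0.1 FPKM (adjusted p = 0.12).

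**Figure D2:**
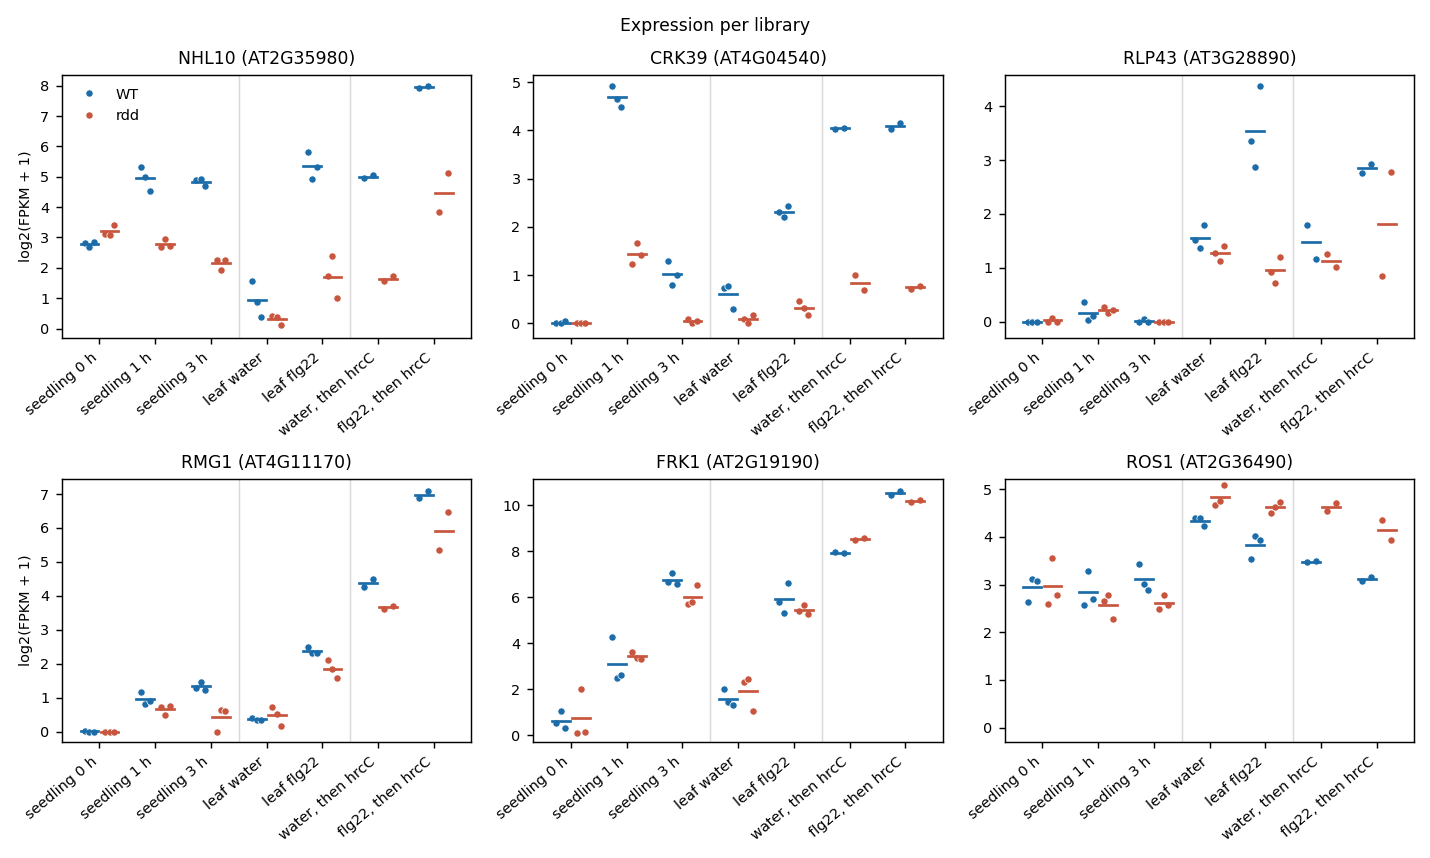
log2(FPKM + 1) (vertical axis) of NHL10, CRK39, RLP43, RMG1, FRK1 and ROS1 in each library over 7 conditions, with WT in blue and rdd in red; points are libraries and bars are group means. NHL10 stood near 30.8 FPKM in WT and 5.87 FPKM in rdd at 1 h, while FRK1 rose in both genotypes.

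The size of the whole response was compared between genotypes over genes called in the mean of both. At 1 h 1143 risen genes had a median log2 fold change of 1.7 in WT and 1.76 in rdd (exact permutation p = 0.675, two-sided), and 262 fallen genes -1.30 and -1.19 (exact permutation p = 0.475). At 3 h 890 risen genes had 1.78 in WT and 1.45 in rdd (exact permutation p = 0.24). The 224 fallen genes had -1.23 and -1.20 (exact permutation p = 0.965). In leaves 1422 risen genes had 1.58 in WT and 1.36 in rdd (exact permutation p = 0.205), and 945 fallen genes -1.64 and -1.23 (exact permutation p = 0.285). In the priming set 961 risen genes had 1.49 and 1.39 (exact permutation p = 0.333) and 1205 fallen genes -1.44 and -1.29 (exact permutation p = 0.389). No difference passed, with Benjamini-Hochberg adjusted p from 0.622 to 0.965 over the 8 tests by exact permutation; the smallest p that the priming design allows is 0.0556. Leaving out 1 library moved the median difference (rdd minus WT) from 0.01 to between -0.27 and 0.25 in the fallen genes at 3 h, and from 0.42 to between 0.15 and 0.65 in those of leaves.

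In leaves the question was the state 24 h after flg22. In WT 2689 genes rose and 1508 fell of 18164 tested, 1345 and 920 by at least 2-fold (limma). The antimicrobial protein gene PR1 (AT2G14610) reached 10485 ± 3597 from 44.7 ± 33.3 FPKM (8.19 ± 0.65), and the chitinase gene CHI (AT2G43570) 966 ± 303 from 14.3 ± 6.28 FPKM (6.02 ± 0.35). The lipid transfer family gene AT4G12490 rose by 5.48 ± 0.50, the trypsin inhibitor gene KTI1 (AT1G73260) by 5.69 ± 1.14 and the calcium exchanger gene CAX3 (AT3G51860) by 5.57 ± 0.39. Among the largest falls were AT2G10940 (-5.80 ± 1.46), the cold-response gene COR15A (AT2G42540, -4.83 ± 1.48), LHCB2.3 (AT3G27690, -4.21 ± 1.11), the carbonic anhydrase gene CA1 (AT3G01500, -4.16 ± 1.12) and the cell wall protein gene PRP4 (AT4G38770, -4.05 ± 0.84).

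Salicylic acid and systemic resistance had 20 of 24 higher and none lower in WT leaves, 21 adjusted over the list alone (median 2.25, camera adjusted p = 7.0e-13, adjusted p = 0.085 with an estimated correlation). PR5 (AT1G75040, 4.59 ± 0.37, 1483 ± 691 against 57.8 FPKM) and the salicylic acid hydroxylase gene DMR6 (AT5G24530, 3.08 ± 0.22) were among them. Early markers had 8 of 21 higher and 1 lower (median 0.57, camera adjusted p = 0.0077, adjusted p = 0.21 with an estimated correlation). NHL10 stood at 41.4 ± 13.1 against 1.03 ± 0.846 FPKM (4.42 ± 0.39) and FRK1 at 64.0 ± 31 against 2.07 ± 0.829 FPKM (4.33 ± 0.42). Perception and signalling had 10 of 25 higher and 1 lower, 14 and 1 adjusted over the list alone (median 0.75, camera adjusted p = 0.00063, adjusted p = 0.21 with an estimated correlation), with the receptor-like gene RLP23 (AT2G32680, 2.24 ± 0.33). Indole glucosinolate and camalexin had 11 of 20 higher and 1 lower, 12 and 1 adjusted over the list alone (median 0.98, camera adjusted p = 0.00045, adjusted p = 0.21 with an estimated correlation), with TSA1 (2.11 ± 0.18) and CYP71A12 (AT2G30750, 2.24 ± 0.28). NLR genes had 6 of 17 higher (median 0.54, camera adjusted p = 0.0057, adjusted p = 0.55 with an estimated correlation), with ADR1 (AT1G33560, 2.11 ± 0.29). Peroxidases had 3 of 5 higher (median 3.04, camera adjusted p = 0.0015, adjusted p = 0.085 with an estimated correlation), with PRX71 (4.71 ± 0.52) and PRX34 (AT3G49120, 3.04 ± 0.30). RMG1 (2.02 ± 0.19, 4.24 ± 0.367 against 0.293 ± 0.032 FPKM) and RLP43 (AT3G28890, 1.98 ± 0.33, 11.8 ± 7.03 against 1.96 ± 0.467 FPKM), a receptor-like protein gene, rose. They were 2 of 5 methylation-dependent loci, 3 adjusted over the list alone (camera adjusted p = 0.20). Of senescence genes 2 of 6 rose, SAG13 (AT2G29350, 4.41 ± 0.35) and PAO (AT3G44880, 1.29 ± 0.35; list camera adjusted p = 0.11).

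Photosynthesis had 18 of 35 lower in WT leaves, 22 adjusted over the list alone (median -1.25, camera adjusted p = 6.9e-12, adjusted p = 0.21 with an estimated correlation), with LHCB1.2 (AT1G29910, -2.65 ± 0.41, 1092 ± 727 against 5992 ± 609 FPKM) and RBCS3B (AT5G38410, -1.91 ± 0.38). Auxin and expansion growth had 6 of 23 lower, 8 adjusted over the list alone (median -1.06, camera adjusted p = 0.00072, adjusted p = 0.55 with an estimated correlation), with LAX2 (AT2G21050, -3.13 ± 0.50) and IAA3 (AT1G04240, -2.46 ± 0.40). Phloem and epidermis markers had 3 of 5 lower, and 3 lower and 1 higher adjusted over the list alone (median -1.47, camera adjusted p = 0.047, adjusted p = 0.21 with an estimated correlation). The 3 were epidermal: ATML1 (AT4G21750, -1.47 ± 0.23), FDH (AT2G26250, -1.87 ± 0.50) and CUT1 (AT1G68530, -1.55 ± 0.45). The methylation machinery had 4 of 32 lower and 1 higher, 2 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.047, adjusted p = 0.61 with an estimated correlation). They included IDM1 (AT3G14980, -0.96 ± 0.17) and ROS1 (-0.51 ± 0.16, 13.4 ± 2.48 against 19.3 ± 1.4 FPKM).

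Leaf libraries of replicate 3 stood apart in both genotypes, with 0.073% to 0.098% of FPKM in organelle genes against 3.03% to 5.54% in replicates 1 and 2. The genes at least 2-fold apart in replicate 3 in all 4 groups were 7 lower and 2 higher of 35 in photosynthesis (median log2 difference -0.74), 7 lower of 23 in auxin (-1), 5 lower and 3 higher of 15 in the clock (-0.78), 4 higher of 12 in aliphatic glucosinolate (1.26) and 3 lower of 6 in senescence (-1.76). There were 0 of 24 in salicylic acid (0.01) and 0 of 25 in perception (0.05), and these counts were not tested. With replicate number as a block 8620 genes were called in WT, and with replicates 1 and 2 only 8766. The call on early markers was lost with replicates 1 and 2 only (adjusted p = 0.096). That on phloem and epidermis was lost with the block (adjusted p = 0.1), with scaling (adjusted p = 0.062) and with replicates 1 and 2 only (adjusted p = 0.097). The higher share was 64.1%, and 51.2% with median-ratio scaling. Without replicate 1 of the WT flg22 leaves 2300 genes were called, and without replicates 1 and 2 of the WT water leaves 2781 and 2679. With only the compared groups in the fit 2439 were, and AT2G10940, CA1, ROS1, PAO, FDH and CUT1 did not pass, while COR15A and LHCB2.3 did not without replicate 1 of the water leaves.

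**Figure D3:**
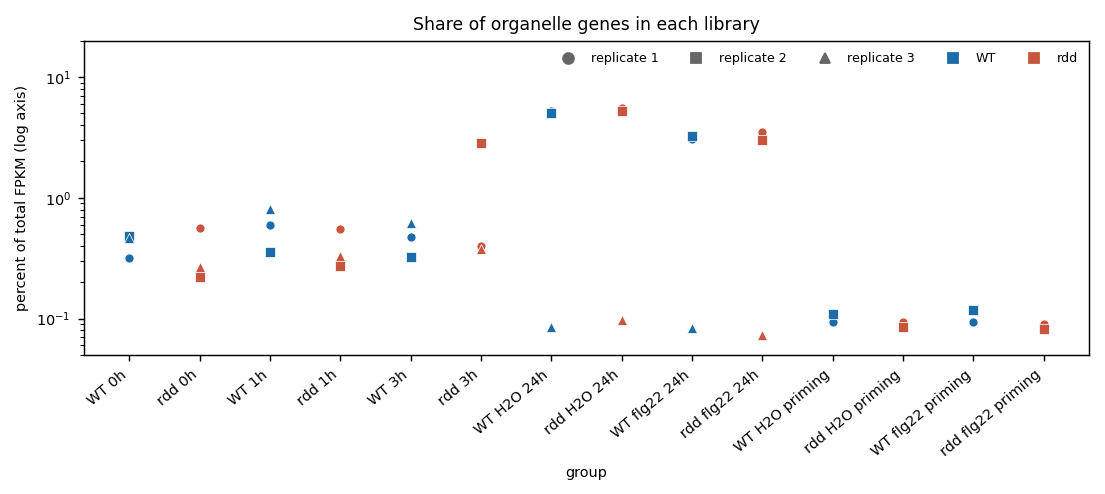
Percent of total FPKM in organelle genes (vertical axis, log scale) in each of the 38 libraries by condition, points shown by replicate number. Leaf replicate 3 lies at 0.073% to 0.098%, below leaf replicates 1 and 2.

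In rdd leaves 2319 genes rose and 675 fell 24 h after flg22, 964 and 400 by at least 2-fold (limma). AT4G12490 (6.34 ± 0.50), AT4G12500 (6.23 ± 0.46), PR1 (5.90 ± 0.65, 8138 ± 2966 against 138 ± 62.5 FPKM), AT2G43620 (5.82 ± 0.44), KTI1 (5.80 ± 1.14) and EARLI1 (AT4G12480, 4.96 ± 0.80) were among the largest rises. STOMAGEN (AT4G12970, -3.30 ± 0.52), a peptide gene that promotes stomata, FAP3 (AT1G53520, -3.29 ± 0.39), AT3G15520 (-2.74 ± 0.37) and AT1G78450 (-2.69 ± 0.40) were among the largest falls. Salicylic acid had 17 of 24 higher, 19 adjusted over the list alone (median 1.55, camera adjusted p = 4.7e-09, adjusted p = 0.12 with an estimated correlation), with DMR6 at 2.30 ± 0.22. Early markers had 7 of 21 higher, 9 adjusted over the list alone (median 0.56, camera adjusted p = 0.0088, adjusted p = 0.18 with an estimated correlation), with FRK1 at 3.52 ± 0.42. Perception had 9 of 25 higher (camera adjusted p = 0.00090) and indole glucosinolate and camalexin 8 of 20, 9 adjusted over the list alone (camera adjusted p = 0.00033), each with adjusted p = 0.12 with an estimated correlation. NLR genes had 6 of 17 higher (camera adjusted p = 0.0019, adjusted p = 0.54 with an estimated correlation). Peroxidases had 3 of 5 higher (camera adjusted p = 0.00068, adjusted p = 0.089 with an estimated correlation). RMG1 rose in rdd (1.36 ± 0.19), while RLP43 was at 0.95 ± 0.328 against 1.41 FPKM (-0.32 ± 0.33, adjusted p = 0.57).

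Photosynthesis had 7 of 35 lower in rdd leaves, 18 adjusted over the list alone (median -1.02, camera adjusted p = 5.4e-14, adjusted p = 0.12 with an estimated correlation). Auxin genes had 3 of 23 lower, 2 adjusted over the list alone (median -0.62, camera adjusted p = 0.0011, adjusted p = 0.56 with an estimated correlation). Guard cell and stomatal lineage genes had 1 of 8 lower, TMM (-1.47 ± 0.28), with a list median of -0.52 (camera adjusted p = 0.0021, adjusted p = 0.12 with an estimated correlation). Cell division genes had 2 of 3 lower, CDKB2;1 (AT1G76540, -1.21 ± 0.20) and KNOLLE (AT1G08560, -1.32 ± 0.23; camera adjusted p = 0.0011, adjusted p = 0.12 with an estimated correlation). The replicate block gave 7490 genes and replicates 1 and 2 only gave 8073. The higher share was 77.5%, and 52.3% with median-ratio scaling, and the median log2 fold change of all genes was 0.178. Leaving out 1 library lowered the count of 2994 to 1268 without replicate 1 and 1668 without replicate 2 of the rdd water leaves, and to 1523 without replicate 1 and 1278 without replicate 2 of the rdd flg22 leaves.

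Between genotypes, water-treated leaves differed in 16 genes, 12 lower and 4 higher in rdd, all by at least 2-fold (limma). AT2G33830 (-5.10 ± 0.60, 95.3 against 3386 FPKM), CRK40 (-2.59 ± 0.35), AT2G40960 (-2.63 ± 0.32), AT3G21400 (-2.25 ± 0.28) and the shoot development gene AMP1 (AT3G54720, -1.53 ± 0.17) were lower. MRD1 and AT4G04223 were listed at 0 in rdd against 22.5 and 38.4 FPKM in WT. TMM (2.30 ± 0.28, 10.7 ± 2.18 against 1.36 ± 0.276 FPKM) and the flowering repressor gene MAF5 (AT5G65080, 2.98 ± 0.40) were higher. Guard cell and stomatal lineage genes were shifted up, with 1 of 8 called and 3 higher adjusted over the list alone (median 0.61, camera adjusted p = 2.7e-16). Salicylic acid genes shifted as well (none called, 2 higher adjusted over the list alone, median 0.23, camera adjusted p = 3.1e-09, adjusted p = 0.19 with an estimated correlation), with PR5 at 280 against 57.8 FPKM (2.27 ± 0.37, adjusted p = 0.094). Abscisic acid genes had a median of -0.03, a mean of 0.12 and an upward camera test (adjusted p = 0.045, adjusted p = 0.55 with an estimated correlation; 0.058 with scaling). Indole glucosinolate genes also shifted (median 0.14, camera adjusted p = 0.045, adjusted p = 0.61 with an estimated correlation), a call lost with the block (adjusted p = 0.14) and with replicates 1 and 2 only (adjusted p = 0.63). The block gave 39 genes, replicates 1 and 2 only gave 26, and leaving out any 1 library gave 2 to 10. With only the compared groups 3 genes passed, and AT2G33830, CRK40, AT2G40960, AT3G21400, AMP1, MAF5 and TMM were not among them.

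In flg22-treated leaves 26 genes were lower and 5 higher in rdd. AT2G25510 (-5.25 ± 0.57, 728 ± 253 against 27556 ± 8152 FPKM), AT4G04223 (-5.76 ± 0.29), AT2G33830 (-5.01 ± 0.60), MRD1 (-3.99 ± 0.22), CRK40 (-3.10 ± 0.35) and NHL10 (-3.65 ± 0.39, 2.52 ± 1.6 against 41.4 ± 13.1 FPKM) were lower. RLP43 was lower too (-2.58 ± 0.33, 0.95 ± 0.328 against 11.8 ± 7.03 FPKM, adjusted p = 0.017, limma). It was 1 of 5 methylation-dependent loci called, 2 adjusted over the list alone (median -0.55, camera adjusted p = 1.2e-05). EMB2656 (AT5G37630, 1.73 ± 0.19) and the small RNA precursor gene TAS3 (AT3G17185, 1.44 ± 0.23) were higher. Guard cell and stomatal lineage genes were shifted up (none of 8 called, 2 higher adjusted over the list alone, median 0.61, camera adjusted p = 7.9e-06). Salicylic acid genes were shifted down (none of 24 called, median -0.37, camera adjusted p = 3.7e-06, adjusted p = 0.17 with an estimated correlation). So were perception genes (median -0.16, camera adjusted p = 0.00062, adjusted p = 0.17 with an estimated correlation). NLR genes had a median of -0.07 (camera adjusted p = 0.028, adjusted p = 0.83 with an estimated correlation), with the direction reversed in replicates 1 and 2 only (adjusted p = 0.85). The block gave 57 genes, replicates 1 and 2 only gave 34, and leaving out any 1 library gave 2 to 18. With only the compared groups 4 genes passed, and NHL10, RLP43, CRK40, AT2G33830, DML3, EMB2656 and TAS3 were not among them.

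No gene passed the leaf interaction in limma, and 257 had an unadjusted p under 0.05 (908 by chance). That fit ignores replicate number, so nothing is read from the shortfall. NHL10 had an interaction of -3.02 ± 0.56 (adjusted p = 0.57), and RLP43 of -2.29 ± 0.47 (adjusted p = 1), so the loss of RLP43 in flg22 leaves is not shown to differ from that in water. As a list, salicylic acid genes responded less in rdd leaves, with a median difference of -0.72 (camera adjusted p = 1.0e-18), and the 3 cell division genes had lower responses (median difference -1.09, camera adjusted p = 3.0e-08), with none of either called over all genes. Adjusted over the list alone, 2 cell division genes and 0 of 24 salicylic acid genes passed. With the block the interaction count was also 0, and 2 genes passed with replicates 1 and 2 only.

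In the priming set the question was how an earlier flg22 treatment changes the state of leaves that meet bacteria. In WT 3991 genes were higher and 4090 lower after flg22 than after water, of 17780 tested, 1032 and 1410 by at least 2-fold (limma). PR1 stood at 7098 ± 1133 against 49.96 ± 3.6 FPKM (7.11 ± 0.18). EARLI1 (5.59 ± 0.21) and AT4G12490 (5.48 ± 0.16) were higher. So were the elicitor-induced gene ELI3-2 (AT4G37990, 4.85 ± 0.38), CHI (4.83 ± 0.25) and the gibberellin-regulated gene GASA5 (AT3G02885, 4.63 ± 0.43). AT2G10940 (-6.00 ± 0.32), LHCB1.2 (-4.15 ± 0.36), COR15A (-3.49 ± 0.48) and the aldolase gene FBA5 (AT4G26530, -3.40 ± 0.36) were lower. All 35 photosynthesis genes were lower (median -1.67, camera adjusted p = 6.0e-17, adjusted p = 0.46 with an estimated correlation). Salicylic acid had 13 of 24 higher and 1 lower (median 0.72, camera adjusted p = 0.00055, adjusted p = 0.46 with an estimated correlation), with PR2 (AT3G57260, 2.80 ± 0.21) and the hydroxylase gene DLO1 (AT4G10500, 3.16 ± 0.18). Aliphatic glucosinolate had 10 of 12 higher, 11 adjusted over the list alone (median 0.99, camera adjusted p = 0.00045, adjusted p = 0.46 with an estimated correlation), with CYP79F1 (AT1G16410, 1.7 ± 0.26). Indole glucosinolate and camalexin had 12 of 21 higher and 2 lower, 13 and 4 adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.46 with an estimated correlation). Peroxidases had 3 of 5 higher (camera adjusted p = 0.013, adjusted p = 0.46 with an estimated correlation). Early markers had 8 of 21 higher and 3 lower, 8 and 4 adjusted over the list alone (camera adjusted p = 0.094), with FRK1 at 1493 ± 130 against 245 ± 6.6 FPKM (2.60 ± 0.10) and NHL10 at 246 ± 6.21 against 31.1 ± 1.5 FPKM (2.95 ± 0.35). RMG1 stood at 126 ± 13.5 against 19.9 ± 2.2 FPKM (2.60 ± 0.31). Of 31 machinery genes 8 were lower and 1 higher, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.051), including the methyltransferase gene CMT2 (AT4G19020, -1.31 ± 0.15) and ZDP (AT3G14890, -1.18 ± 0.14). Without replicate 1 of the water group 3273 genes were higher and 2886 lower, and without replicate 2 of the flg22 group 5334 were called.

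In rdd 3916 genes were higher and 3310 lower after flg22 in this set, 963 and 1099 by at least 2-fold. GASA5 (6.19 ± 0.43), AT4G12490 (5.89 ± 0.16), DXPS1 (AT3G21500, 5.71 ± 0.33) and PR1 (4.39 ± 0.18, 4850 ± 935 against 230 ± 29 FPKM) were higher. AT2G10940 (-5.94 ± 0.32), GER3 (AT5G20630, -3.83 ± 0.30), LHCB1.2 (-3.72 ± 0.36) and the heat stress factor gene HSFA2 (AT2G26150, -3.14 ± 0.38) were lower. Photosynthesis again had all 35 lower (median -1.69, camera adjusted p = 3.2e-20, adjusted p = 0.53 with an estimated correlation). Salicylic acid had 13 of 24 higher and 1 lower (camera adjusted p = 0.013) and jasmonate and ethylene 8 of 25 higher (camera adjusted p = 0.017), each with adjusted p = 0.55 with an estimated correlation. Aliphatic glucosinolate had 8 of 12 higher, 10 adjusted over the list alone (camera adjusted p = 0.0076, adjusted p = 0.55 with an estimated correlation). Guard cell genes were lower in 5 of 8 (median -0.67, camera adjusted p = 0.0093, adjusted p = 0.53 with an estimated correlation), with MYB60 (AT1G08810, -1.25 ± 0.12). Phloem and epidermis genes were lower in 4 of 5 (median -0.96, camera adjusted p = 0.016, adjusted p = 0.53 with an estimated correlation), with CUT1 (-1.45 ± 0.10). NHL10 rose here in rdd (2.83 ± 0.35) but to 23.6 ± 14.5 FPKM, RMG1 rose by 2.26 ± 0.31, and DML2 (-0.81 ± 0.20) and ROS1 (-0.48 ± 0.14) fell, each passing in 1 of 4 fits with 1 library left out. Without replicate 2 of the flg22 group 4751 genes were called.

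After water and then bacteria, 114 genes were higher and 54 lower in rdd than in WT, 56 and 40 by at least 2-fold. Salicylic acid had 4 of 24 higher, or 7 higher and 2 lower adjusted over the list alone (median 0.17, camera adjusted p = 0.0027, adjusted p = 0.31 with an estimated correlation). They were PR1 (2.17 ± 0.18, 230 ± 29 against 49.96 ± 3.6 FPKM), PR5 (2.36 ± 0.33, 383 ± 38.2 against 73.8 ± 3.46 FPKM), PR2 (1.52 ± 0.21) and DLO1 (1.43 ± 0.18). CYP97B3 (3.12 ± 0.12), CHI (1.96 ± 0.25), CYP71A12 (1.85 ± 0.14), IGMT1 (AT1G21100, 1.46 ± 0.19) and FRK1 (0.61 ± 0.10) were also higher. AT2G33830 (-5.87 ± 0.23), AT4G11000 (-4.25 ± 0.20), GSTU4 (AT2G29460, -3.79 ± 0.45) and NHL10 (-3.35 ± 0.35, 2.14 ± 0.24 against 31.1 ± 1.5 FPKM) were lower. CRK39 (-3.20 ± 0.15), QQS (-3.10 ± 0.23) and CYP79F1 (-1.68 ± 0.26) were also lower, and MRD1, AT3G01345 and AT4G04223 were listed at 0 in rdd. Guard cell and stomatal lineage genes had 2 of 8 higher, 5 adjusted over the list alone (median 0.75, camera adjusted p = 1.7e-08, adjusted p = 0.06 with an estimated correlation). They were MYB60 (0.90 ± 0.12) and FAMA (AT3G24140, 0.79 ± 0.11). Indole glucosinolate had 2 of 21 higher, 4 adjusted over the list alone (median 0.25, camera adjusted p = 1.7e-06, adjusted p = 0.31 with an estimated correlation). Leaving out any 1 library gave 35 to 75 genes in place of 168, with 16 higher and 19 lower without WT replicate 2 and 22 and 30 without rdd replicate 2, the block gave 100, and with only the compared groups 87. PR5, PR2, DLO1, CHI, FRK1, MYB60, FAMA, ROS1, NHL10 and CYP79F1 did not pass in any fit with 1 of the 4 libraries left out.

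After flg22 and then bacteria, 259 genes were higher and 111 lower in rdd, 162 and 59 by at least 2-fold. Among the largest differences were the jasmonate-responsive storage protein genes VSP1 (AT5G24780, 4.74 ± 0.83, 58.8 against 1.24 FPKM) and VSP2 (AT5G24770, 3.85 ± 0.58), BGLU18 (AT1G52400, 3.96 ± 0.63), the methyltransferase gene BSMT1 (AT3G11480, 3.12 ± 0.24) and DXPS1 (2.92 ± 0.33). CYP71A12 was higher by 1.5 ± 0.14. Jasmonate and ethylene had 2 of 25 higher, 4 adjusted over the list alone (median 0.58, camera adjusted p = 0.0045, adjusted p = 0.72 with an estimated correlation). AT3G01345 (-6.71 ± 0.10), MRD1 (-4.93 ± 0.18), AT2G33830 (-4.92 ± 0.23), NHL10 (-3.47 ± 0.35, 23.6 ± 14.5 against 246 ± 6.21 FPKM), CRK39 (-3.35 ± 0.15) and CYP79F1 (-2.33 ± 0.26) were lower. Early markers had 1 of 21 lower, or 5 lower and 1 higher adjusted over the list alone (median -0.26, camera adjusted p = 0.0045, adjusted p = 0.46 with an estimated correlation). Methylation-dependent loci had 1 of 5 lower, 2 adjusted over the list alone (median -1.04, camera adjusted p = 0.024, adjusted p = 0.46 with an estimated correlation). RMG1 had a difference of -1.06 ± 0.31 (adjusted p = 0.15, limma). Salicylic acid had 1 of 24 higher, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.52). Leaving out any 1 library gave 74 to 204 genes in place of 370, with 51 higher and 62 lower without rdd replicate 1, and VSP1, VSP2 and BGLU18 passed in none of those fits.

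The priming interaction passed for 17 genes, 9 higher and 8 lower (limma). PR1 responded less in rdd (-2.73 ± 0.25, adjusted p = 0.026), as did WRKY6 (AT1G62300, -1.32, adjusted p = 0.027), PCR1 (AT1G14880, -1.72, adjusted p = 0.03) and PNP-A (AT2G18660, -1.48, adjusted p = 0.047). WRKY6 was at 238 FPKM in rdd and 98 in WT after water and 494 and 515 after flg22 (PCR1 809 and 1746). BSMT1 (3.07, adjusted p = 0.038) and DGL (AT1G05800, adjusted p = 0.027), listed at 0 in WT after water, responded more. Most fits with 1 library left out lost each of these 6.

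Some genes differed between rdd and WT whatever the condition. MRD1, AT4G04223, AT2G33830, CRK40 and AT3G21400 were lower in all 5 conditions with 3 replicates, and 0 genes were higher in all 5. Over all 7 conditions the mean log2 fold changes were -4.35 for AT2G33830, -3.33 for CRK40 and -1.9 for AT3G21400. MRD1 and AT4G04223 were listed at 0 in rdd in some conditions. In at least 3 of 7 conditions 34 genes were lower and 12 higher, and 0 changed direction. TMM and CYP97B3 were each higher in 4 conditions, and NHL10 and CRK39 lower in 5. The genes lower at 0 h and at 1 h shared 25, where 0.0722 would come by chance (Fisher's exact test, two-sided, adjusted p = 4.2e-63), and those higher shared 9, where 0.0207 would (adjusted p = 8.4e-23 by Fisher's exact test). Seedlings at 0 h and water-treated leaves shared 7 lower genes, where 0.0205 would come by chance (adjusted p = 2.2e-17 by Fisher's exact test). Of 42 overlaps tested 34 passed; the genes higher in water-treated and in flg22-treated leaves shared 0.

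**Figure D4:**
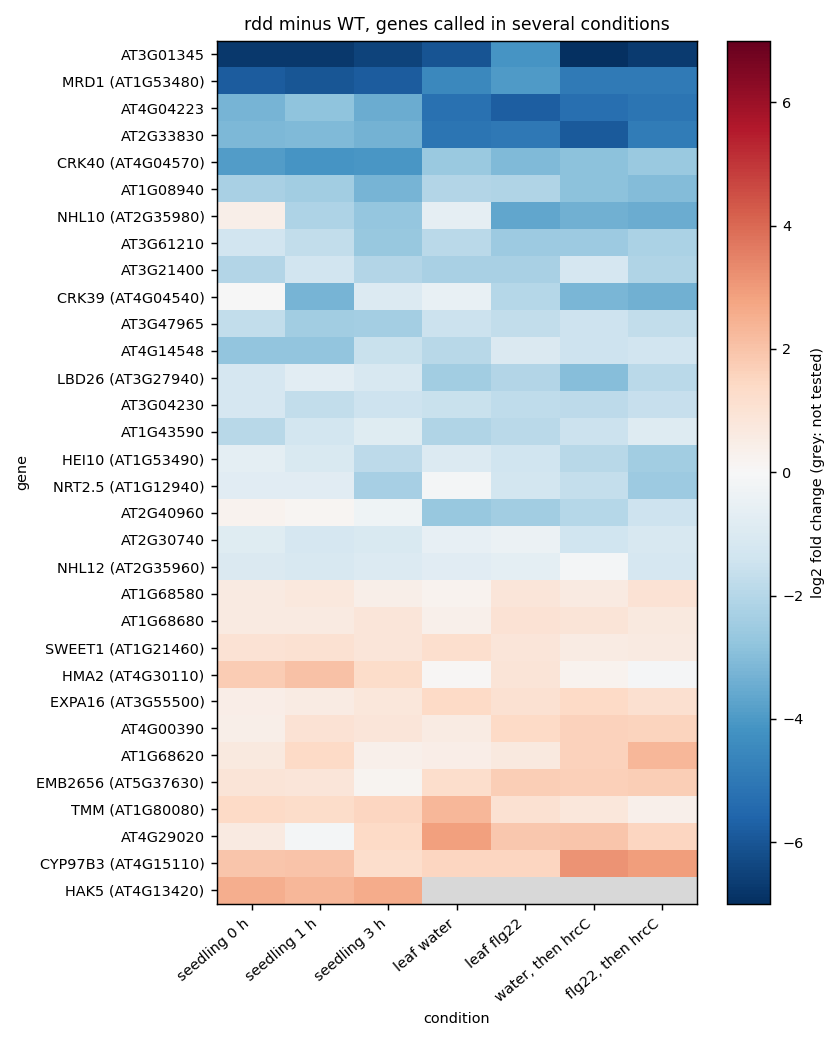
Log2 fold change of rdd minus WT (colour, log2 of FPKM + 1) of the genes called in the most conditions, with genes down and the 7 conditions across; grey marks genes not tested. CRK40, with a mean of -3.33, was called lower in all 7 and TMM was called higher in 4.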

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

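The test of harvest at another time of day was written after the result was seen. All results in the next 3 paragraphs were singled out because the effect of flg22 differed between WT and rdd in a test of the difference itself; values are differences of log2 fold changes, rdd minus WT, and for CRK39, DGL and AT3G22183, at 0 in 1 or more groups, the added 1 FPKM sets their size.

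In seedlings the genes were CRK39 (-3.23, adjusted p = 7.8e-06, limma) and NHL10 (-2.58, adjusted p = 0.00015) at 1 h and NHL10 (-3.10, adjusted p = 2.1e-05) at 3 h. Splits of genotype labels gave at least 2 genes in 3 of 100 for 1 h. The highest other split gave 3 and exchanged only replicate 1 at 0 h. For 3 h 16 of 100 gave at least 1 gene. The highest, with 5, exchanged all 3 h libraries and replicate 2 at 0 h. Such uneven exchanges leave genotype differences in the interaction, so the splits cannot decide on chance. Of the lists at 1 h, salicylic acid had a median of 0.36 (camera adjusted p = 0.0011), jasmonate and ethylene 0.67 (3.5e-09), indole glucosinolate and camalexin 0.37 (4.5e-05) and aliphatic glucosinolate 0.34 (3.7e-05); with an estimated correlation their adjusted p were 0.58, 0.35, 0.58 and 0.35. At 3 h jasmonate and ethylene had 0.04 (mean -0.01, upward camera test, adjusted p = 0.03), aliphatic glucosinolate 0.03 (0.013), photosynthesis 0.13 (2.0e-07), root markers 0.3 (0.0092), phloem and epidermis 0.07 (0.048) and senescence -0.85 (0.013), none past 0.05 with an estimated correlation (adjusted p = 0.31 the lowest). The median log2 difference of all genes at 3 h was -0.198.

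In leaves no single gene passed in limma. Of 100 splits 100 gave at least as many as the real 0, and the highest gave 53. That split exchanged WT and rdd in the flg22 leaves alone, so it summed the genotype differences of both treatments, a structure of the samples. Salicylic acid genes had a median difference of -0.72 (camera adjusted p = 1.0e-18; adjusted p = 0.043 with an estimated correlation), cell division genes -1.09 (3.0e-08; adjusted p = 0.043 with an estimated correlation) and methylation-dependent loci -0.01 (0.017; adjusted p = 0.097 with an estimated correlation).

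In the priming set 17 genes were singled out, each by limma. PR1 (-2.73, adjusted p = 0.026), AT4G39404 (-2.42, 0.026), WRKY6 (-1.32, 0.027), PCR1 (-1.72, 0.03), AT3G18250 (-2.29, 0.036), PNP-A (-1.48, 0.047), AT2G36690 (-2.04, 0.047) and AT5G44578 (-2.51, 0.047) responded less or in the lower direction in rdd. AT1G24881 (1.96, adjusted p = 0.026), AT3G22183 (2.76, 0.026), AT2G17500 (2.22, 0.026), DGL (2.45, 0.027), BSMT1 (3.07, 0.038), AT4G02320 (2.85, 0.038), AT4G31290 (1.37, 0.044), SAUR24 (1.63, 0.047) and LSH1 (1.87, 0.047) went the other way. The lists were early markers (median -0.23, camera adjusted p = 2.9e-05), perception (-0.19, 0.011), salicylic acid (-0.3, 0.0026), jasmonate and ethylene (0.48, 0.048), indole glucosinolate (-0.17, 0.0053), aliphatic glucosinolate (-0.3, 0.014), methylation machinery (0.1, 0.048), peroxidases (-0.28, 0.038), guard cell (-0.17, 0.048), phloem and epidermis (-0.37, 0.00060) and cell division (-0.66, 0.014), none past 0.05 with an estimated correlation (adjusted p = 0.22 the lowest). With the replicate block 1 gene passed.

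The first pattern weighed is the larger number of genes that differed between rdd and WT at 3 h (180) than at 0 h (61) or 1 h (54). If rdd replicate 2 at 3 h, with the fewest genes above 0, made those calls, the count without it would fall to 61. It was 124, with 94 of the 180 kept, but 61 and 54 come from fits that hold this library, so this cannot decide. With only the compared groups fitted, counts were 26, 45 and 30, so 3 h did not have the most. Those fits also differ in degrees of freedom and genes tested, and the cause was not tested. Leaving out another 3 h library gave 81, 65 and 77 (WT replicates 1, 2 and 3), 83 (rdd replicate 1) and 1709 (rdd replicate 3), each above 61. A biological explanation, a genotype difference that grows with time after flg22, may stand but was not told from the hour of sampling.

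The second pattern is the set of 46 genes that differed between rdd and WT in at least 3 of 7 conditions. By position, 4.3% of the 46 lay within 200 genes of ROS1, DML2 or DML3 (2 genes, exact 95% interval 0.5% to 14.8%), against 4.6% of tested genes. This argues against linked segments of that size as the cause. Longer ones were not tested, and many of the 46 lie on chromosome 4 from AT4G00390 to CYP97B3. Segments from another strain elsewhere stay open: 11 pairs of the 46 lay within 50 genes of each other, as such segments would give. Of 10000 random draws 18 gave as many (median 3, permutation p = 0.002). Tandem copies such as CRK39 and CRK40 are among the pairs, so neighbours sharing a methylation change could give this too. Methylation was not analysed. NHL10 and NHL12 lie 60 and 62 genes from ROS1, AT2G33830 319, AT2G40960 500 and AT2G30740 685, and linked variants were not tested.

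The third pattern is that leaf replicate 3 stood apart from replicates 1 and 2 in all 4 groups. A batch that kept or lost organelle RNA alone would leave nuclear genes in place, but 6.74% of 18062 nuclear genes (664 higher and 554 lower) differed at least 2-fold the same way in all 4 groups, which argues against it. Harvest at another time of day may be a cause, since 53.3% of the 15 clock genes did so, with CCA1, LHY, PRR9, RVE8 and LNK2 lower and TOC1, ELF4 and BOA higher in replicate 3. No biological explanation was tested, since the design names none for replicate numbers.

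For the comparisons with 3 libraries against 3, the 10 splits are too few for a share under 0.05, and 1 split, the real 1, reached the real count in each. With only the compared groups in the fit, the real count and the highest other were 3648 and 1 for flg22 at 1 h in WT, 5227 and 1 at 3 h in WT, 2715 and 1 at 1 h in rdd, and 894 and 0 at 3 h in rdd. For rdd against WT they were 26 and 3 at 0 h, 45 and 2 at 1 h, and 30 and 2 at 3 h. In leaves they were 2439 and 1 for flg22 in WT, 1460 and 1 in rdd, 3 and 1 for rdd against WT after water, and 4 and 2 after flg22. Leaf replicate 3 stood apart, while pairing of leaf replicates 1 and 2 is not shown. Among the 4 splits that part 3 same-numbered pairs, as the real 1 does, the highest other was 1 for flg22 in WT. It was 0 in the remaining leaf comparisons. Among the 6 splits that part fewer pairs the highest was 2.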

How the results depend on the processing

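Leaf replicates 1 and 2 only, a pseudocount of 0.1 FPKM, a permutation within replicate numbers and gene lists without doubted libraries were chosen after the data were seen. Where a value changed, the cause was not tested unless stated.

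Of 361 list tests 142 passed; 136 passed with median-ratio scaling (131 shared), 142 with replicate number as a block (134 shared) and 19 with an estimated correlation. Of the list calls at 3 h 18 stayed and 5 were lost without rdd 3 h replicate 2: aliphatic glucosinolate in the rdd response (adjusted p = 0.057), photosynthesis between genotypes (0.075), and jasmonate and ethylene (0.072), aliphatic glucosinolate (0.072) and phloem and epidermis (0.13) in the interaction. With leaf replicates 1 and 2 only 29 stayed and 6 were lost, 3 of them given in the report, and phloem and epidermis in rdd (adjusted p = 0.078), cell division in rdd against WT after water (0.08) and methylation-dependent loci in the interaction (0.13). The difference in response size was -0.57 for the 3 h lower genes chosen by calls in rdd alone (exact permutation p = 0.03, unadjusted), a choice that itself favours a larger response in rdd, so no difference is read from it. Leaf replicates 1 and 2 only gave 8766 genes for flg22 in WT, 8073 in rdd, 26 for rdd against WT after water and 2 for the interaction, and the NLR list after flg22 changed direction (adjusted p = 0.85). Median-ratio scaling gave 283 genes for rdd against WT at 3 h and 1 for the leaf interaction. No filter gave 1 for the leaf and 8 for the priming interaction. A pseudocount of 0.1 gave 1 for the 1 h and 8 for the priming interaction. With only the compared groups in the fit, which have fewer residual degrees of freedom, counts were 894 for flg22 at 3 h in rdd, 26 and 30 for rdd against WT at 0 and 3 h, 2439 and 1460 for flg22 in WT and rdd leaves, 3 and 4 for rdd against WT leaves after water and flg22, and 87 for priming after water. The replicate block gave 8620 and 7490 for flg22 in WT and rdd leaves, 39 and 57 for rdd against WT leaves, 100 for priming after water and 1 for the priming interaction.

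Leaving out each library in turn gave these ranges, with libraries that moved a count by over 1.5 times named. In seedlings flg22 gave 2350 to 3179 at 1 h and 2557 to 3027 at 3 h in WT, 2394 to 3044 at 1 h in rdd and 1971 (without rdd 0 h replicate 3) to 4139 at 3 h in rdd. Seedling rdd against WT gave 34 (without WT replicate 3; 40 without rdd replicate 3) to 50 at 0 h, 27 (without rdd replicate 1; 29 without WT replicate 3) to 47 at 1 h, and 65 to 1709 at 3 h (WT replicates 1, 2 and 3 gave 81, 65 and 77, rdd replicates 1 and 3 gave 83 and 1709). The 1 h interaction gave 2 to 3 and the 3 h interaction 1 to 3 (3 without rdd 3 h replicate 2; 2 without rdd 3 h replicate 3, rdd 0 h replicate 1 or WT 3 h replicate 3). Leaf flg22 gave 2300 to 3909 in WT (without water replicates 1 and 2, 2781 and 2679; without flg22 replicate 1, 2300) and 1268 to 3208 in rdd (without water replicates 1 and 2, 1268 and 1668; without flg22 replicates 1 and 2, 1523 and 1278). Leaf rdd against WT gave 2 to 10 after water and 2 to 18 after flg22, each of the 6 libraries moving the count, and the leaf interaction 0 to 1 (1 without WT water replicate 1). Priming gave 5334 (without WT flg22 replicate 2) to 6159 in WT, 4751 (without rdd flg22 replicate 2) to 5686 in rdd, 35 to 75 and 74 to 204 for rdd against WT after water and flg22, each of the 4 libraries moving the count, and 0 to 30 for the interaction, where each of the 8 did (0 without WT flg22 replicate 2, 30 without rdd water replicate 2). Where a priming group was left with 1 library, that library was assumed to vary like the other groups. The planned DESeq2 and edgeR alternatives need counts and were not run.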

Other observations

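Some gene groups changed in comparisons described above without being named there. At 3 h of flg22 in rdd seedlings salicylic acid genes had 8 of 20 higher, 9 adjusted over the list alone (camera adjusted p = 1.7e-05, adjusted p = 0.15 with an estimated correlation). Jasmonate and ethylene had 11 of 25 higher, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.4e-08, adjusted p = 0.15 with an estimated correlation). Peroxidases and callose had 5 of 7 higher (median 1.72, camera adjusted p = 1.3e-07), with PRX33 (AT3G49110, 1.72 ± 0.13) and PRX71 (3.28 ± 0.41). Root markers had 2 of 16 lower (median -0.37, camera adjusted p = 0.038, adjusted p = 0.35 with an estimated correlation), EXPA18 (AT1G62980, -1.14 ± 0.20) and PYK10 (-0.59 ± 0.17).

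Between rdd and WT, 1 of 8 guard cell and stomatal lineage genes was higher after flg22 and then bacteria, 5 adjusted over the list alone (median 0.47, camera adjusted p = 0.00053, adjusted p = 0.27 with an estimated correlation), MYB60 at 0.75 ± 0.12. After water and then bacteria the phloem and epidermis list was shifted up (median 0.26, camera adjusted p = 0.00066, adjusted p = 0.31 with an estimated correlation), with the epidermal gene PDF1 (AT2G42840) at 1.65 ± 0.16, which was also higher in rdd seedlings at 3 h (1.02 ± 0.17, 211 against 104 FPKM). TMM was higher in rdd in 4 of 7 conditions, while EPF2 was lower at 3 h.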
